A study of Mus musculus with 21 samples.

How the data were processed

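Total RNA came from 21 tissue samples of mouse skin, 3 each of intact skin and of wound bed and wound edge at 2, 6 and 15 days after wounding. Per the labels, 3 animals were used for each time point, and the labels do not say whether a bed and an edge sample came from the same animal. The bed labels also mention skin of the operation day, and the samples were taken as wound bed of the stated day, as their titles name them. Per the labels' protocols, 500 ng of total RNA was amplified, labelled with Cy3 and hybridised to an array of oligonucleotide spots, with 1 colour per array.

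The authors deposited the scanner output of each array, in which a spot's brightness is an intensity on a linear scale up to 65535. Per the file headers, the spots were quantified by image analysis of a 532 nm scan with software of version 4.1 and automatic segmentation. Each array had 13824 spots, namely 1687 probes with 8 spots each and 328 blank or empty spots (168 and 160). The deposited files also hold a flag from 0 to 3 for each spot as another kind of value, with its meaning not given in the sources used here. The authors also deposited a table of the whole series that holds a scaled log score for each probe. Its values were rebuilt from the scanner output as the log of the mean spot signal over the spots without flag 1, shifted and scaled within each array to a median of 1 and an SD of 0.2, with no background subtraction. The rebuilt and deposited values differed by at most 0.00119, which settles the scale, centring and direction of that table. The medians of its columns ran from 0.999 to 1.00.

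The comparisons and tests had been fixed before the data were examined, for another scanner format with a processed signal scaled to the 75th percentile. The files held another format, so the intensities were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3 (signal mean against local background median, offset 50). The mean log2 value over the spots of a probe without flag 1 was taken, and the arrays were quantile normalized. Quantile normalization makes the distribution of signals equal on all arrays, so a shift of most transcripts in one direction would not show. The 75th percentile became an alternative. A probe counted as detected on an array when its mean log2 signal was above the 95th percentile of that array's blank and empty spots, and 974 probes detected on at least 3 of the 21 arrays were tested. A total of 713 were not tested, and 323 were detected on all 21. Where a probe was detected on no array of a group, its fold is given only as a bound. On the dimmest array by this measure 54.0% of the blank and empty spots were brighter than the median probe, and on the best 2.44%.

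A linear model with a mean for each of the 7 groups was fitted to all 21 arrays with limma, which pools the spread over the groups (14 residual degrees of freedom), and moderated by empirical Bayes. There were 13 comparisons of pairs of groups, and an F-test of whether the difference between bed and edge changes with the day. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a probe was called at an adjusted p below 0.05. Values are mean ± SD over 3 arrays. P-values measure the spread between these samples.

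The rule for named genes, set before the data were examined, took the 6 largest rises and falls among called genes of each comparison (the 5 largest over time) and called members of 38 lists of 904 gene symbols, such as heparan sulfate enzymes, collagens, cytokines and cell type markers. A gene without a symbol was to be passed over. The files do not pair probes with gene symbols. Of the 1687 probes, 1612 carry a catalogue identifier and 75 a public identifier, 55 of them a UniGene cluster. Through a RefSeq gene table (assembly GRCm38.p6), 3 probes matched by accession, to Fbln1, Hpse and Ndst3, each of which stands in a different list. The lists could therefore not be tested, no list result is given, and no genome positions are given. The 4 catalogue probes in the text were chosen after the values were seen.

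The 21 arrays were on 21 slides, so slide could not be a block. The images were scanned on 3 days. Scan day 1 held intact replicate 1 and edge replicates 1 and 2 of each day, scan day 2 held intact replicates 2 and 3, bed replicate 1 and edge replicate 3 of each day, and scan day 3 held bed replicates 2 and 3 of each day. Scan day as a block and the values within a scan day are given with each comparison. In the blocked fit the scan day itself had an effect at an adjusted p below 0.05 on 2 of the 974 probes, and at an unadjusted p below 0.05 on 94. Without any effect, a share of 0.05 of the probes passes that unadjusted threshold on average.

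The fits were tested on simulated data made from the means and spreads of the 974 probes, with 200 probes changed in the bed at day 2 in each of 20 runs. For the bed at day 2 against intact skin, 34.7% of the 2-fold and 88.2% of the 4-fold changes were recovered, and 4.28% of the calls were false. With a simulated shift on scan day 3, 9.10% of the calls were false without a block, and 4.94% with scan day as a block, which recovered 75.5% of the 4-fold changes. The F-test recovered 57.4% of the 4-fold changes. The simulated noise was independent and normal, with 1 spread per probe for all groups, and the size of the scan shift was chosen freely. The real groups differed in how well their arrays matched (r within groups 0.770 to 0.982). These shares may therefore not hold for the groups with a larger spread.

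The alternatives tried were other scalings (75th percentile, median, 75th percentile over the probes detected on all arrays), other filters on dim probes, the deposited table, the arrays of the compared groups alone, another variance model, the replicate number and the scan day as blocks, stricter thresholds, and leaving out each array in turn. For bed against edge and for the F-test, the replicate block was the replicate number within each day. It thus treated same-numbered bed and edge arrays of a day as pairs, which the labels do not state. After the data were examined, 4 more were added, namely no background correction, the median over the spots, keeping spots with flag 1, and leaving out the 3 arrays with a median spot under 1.3 times the local background (intact replicate 2, edge day 2 replicate 3 and edge day 15 replicate 3). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and files were read with pandas 2.3.3 and numpy 2.4.6.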

Results

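Gene expression was measured in skin wounds of female mice of the strain C57Bl/KS-db/+, which carry a single copy of db, a mutation of the leptin receptor. A piece of back skin of 1.5 by 1.5 cm had been excised together with the muscle layer below it, and the tissue was taken 2, 6 or 15 days later. The wound bed is the tissue within the excised area. The wound edge is a strip of skin, 2 mm wide, around it. Intact skin served as the control. The 21 arrays fell into 7 groups of 3, namely intact skin, and bed and edge at each of the 3 days. The series is titled for heparan sulfate, a sulfated sugar chain on cell-surface and matrix proteins, and the comparisons ask how transcripts of the wound differ from those of intact skin, between bed and edge, and over time. Each array carried 1687 probes, of which 487 to 934 per array were brighter than 95% of that array's blank spots. The median spot signal was 1.25 to 2.43 times the local background. With 3 arrays a group, the number of arrays limits the precision of every value.

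Only 3 of the 1687 probes could be given a gene symbol, so most results below are counts of probes. The 3 were Hpse, Fbln1 and Ndst3. Hpse encodes heparanase, the enzyme that cleaves heparan sulfate chains. Fbln1 encodes fibulin-1, a protein of the extracellular matrix. Ndst3 encodes an enzyme that modifies heparan sulfate chains, and its probe was not brighter than the blank spots on any of the 21 arrays, so no level is given for it. Of the remaining probes, 2 that rose and 2 that fell are given by their catalogue identifiers. They were chosen after their values were seen, as those found most often among the largest changes from intact skin.

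Arrays of a group correlated with each other across the 974 tested probes with r of 0.770 to 0.982, where probes are not independent replicates. As a check for a repeated deposit of the same array, the median difference of the closest pair in a group was 1.90 times the error of its spots, against 0.674 for arrays that do not differ. This check says nothing of the spread between animals. Bed day 15 replicate 1 correlated with the 3 bed day 2 arrays at a mean r of 0.899 and with the other 2 bed day 15 arrays at 0.808.

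**Figure D1:**
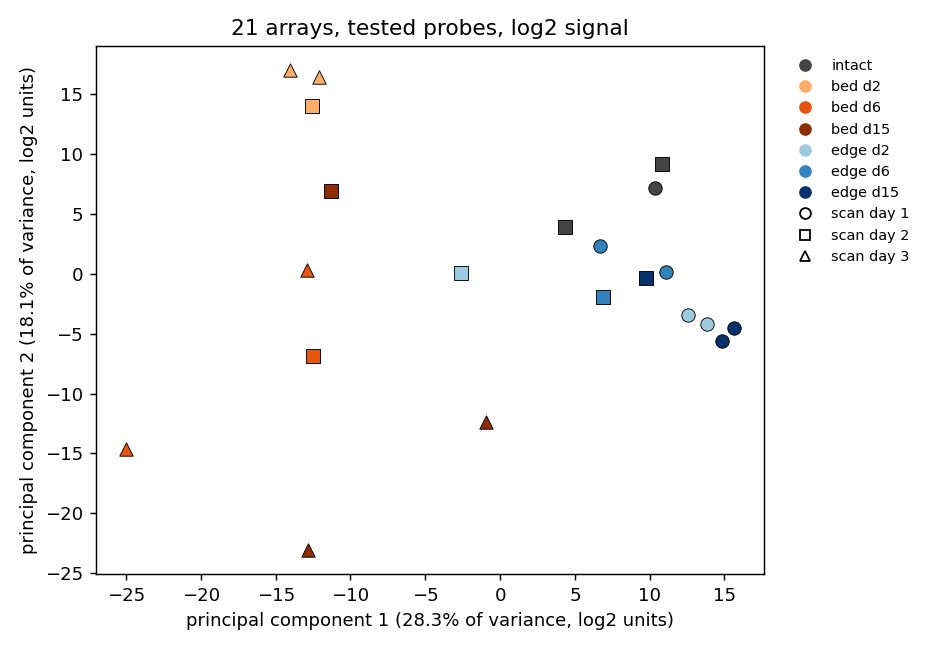
Principal components 1 and 2 (28.3% and 18.1% of the variance, log2 units) of the 21 arrays over the tested probes, coloured by group, with the scan day as the shape. Intact skin and edge lie to the right of all 9 bed arrays except edge day 2 replicate 3, which lies to the left of bed day 15 replicate 2, and on component 2 bed day 15 replicate 1 lies between the bed arrays of day 2 and those of day 6.

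**Figure D2:**
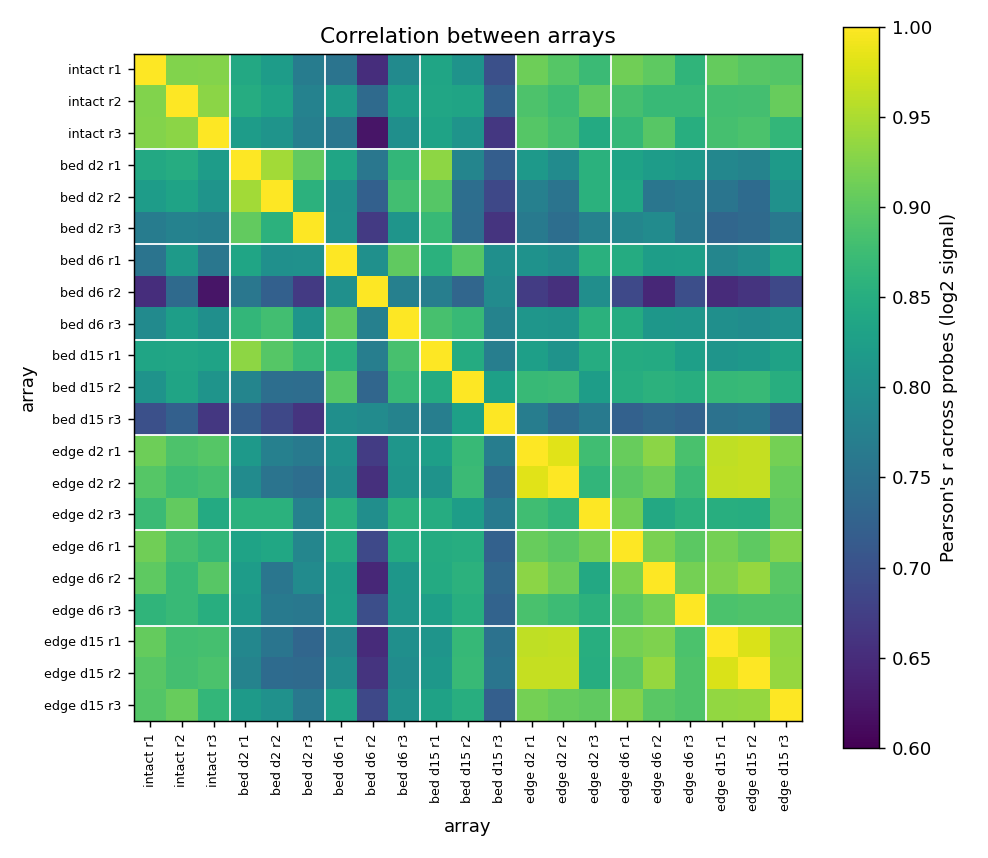
Pearson's r across the tested probes between every pair of the 21 arrays, with lines between groups. Within groups r ran from 0.770 to 0.982, and the highest r between groups, 0.965, joins edge arrays of day 2 and day 15.

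Heparanase had its highest mean signal in the bed at day 6. The Hpse probe had a log2 signal of 11.17 ± 0.27 there (SD, n = 3), against 10.67 ± 0.06 in the bed at day 2 and 10.82 ± 0.63 at day 15. Intact skin had 10.37 ± 0.57, and the edge had 10.28 ± 0.18, 10.17 ± 0.10 and 10.28 ± 0.11 at days 2, 6 and 15. Hpse was higher in the bed than in the edge at day 6 by 1.0 on the log2 scale (SE 0.32, limma adjusted p = 0.0427), with all 3 bed arrays above all 3 edge arrays. This call did not hold with scan day as a block (0.76, SE 0.41, adjusted p = 0.422), and on scan day 2 alone the bed array read 11.49 and the edge array 10.06. It was lost in 14 of the 21 settings tried, over which the adjusted p ranged from 0.0343 to 0.422, and among them when any 1 of the 6 arrays was left out (adjusted p = 0.114, 0.0665 and 0.0528 without bed day 6 replicates 1, 2 and 3, and 0.0817, 0.110 and 0.107 without edge day 6 replicates 1, 2 and 3). Without any 1 of these arrays the log2 difference lay between 0.84 and 1.10, and with the median of each array as the scale it was 0.46 (adjusted p = 0.358). Against intact skin, the bed at day 6 differed by 0.80 (SE 0.32, adjusted p = 0.0858), which did not pass the threshold. Without intact replicate 2, the brightest of the 3 intact arrays for this probe, the difference was 1.13 and passed (adjusted p = 0.0272). No other comparison called Hpse. Fbln1 was called in none of the 13 comparisons, and its mean log2 signal lay between 9.80 ± 0.10 in the bed at day 2 and 10.90 ± 0.62 in the bed at day 15. In intact skin Fbln1 had 10.12 ± 0.42, with 2 of the 3 arrays brighter than the blank spots.

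**Figure D3:**
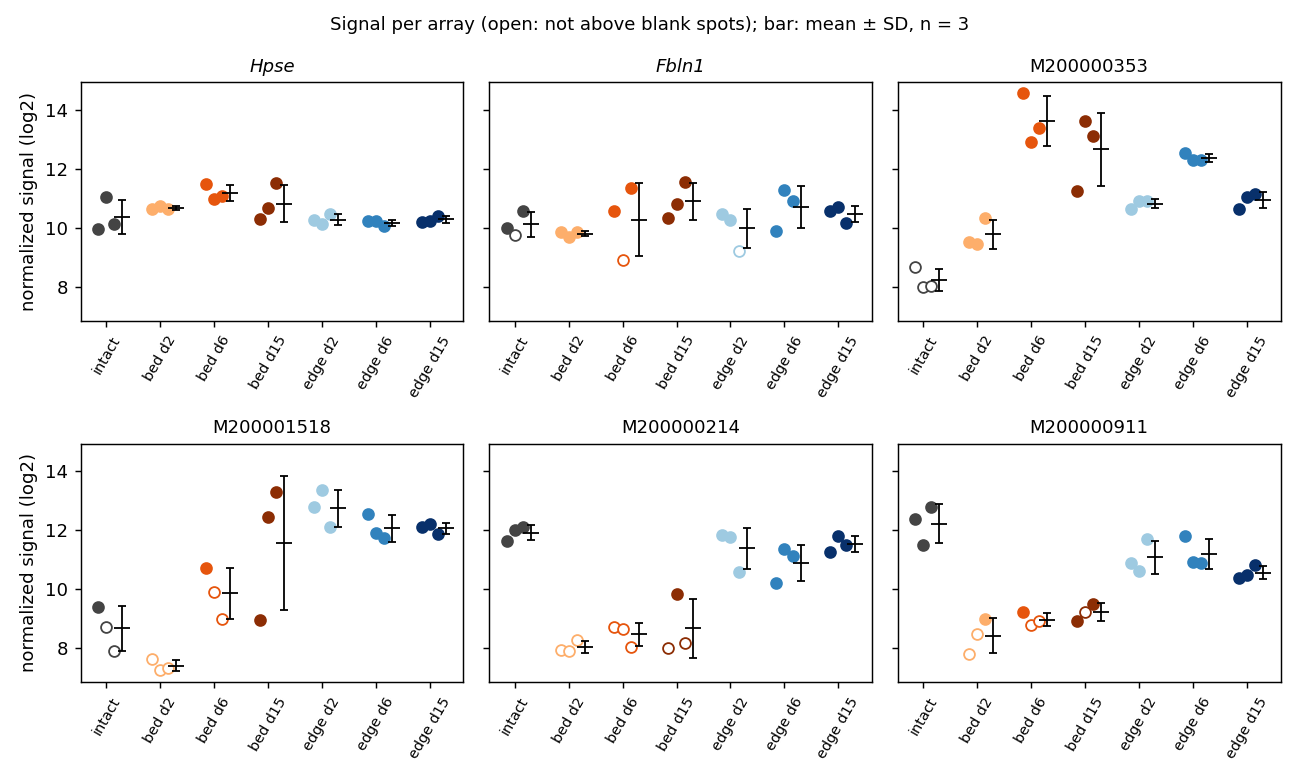
Normalized log2 signal of Hpse, Fbln1 and 4 catalogue probes on each of the 21 arrays by group, with open points for arrays on which the probe was not brighter than 95% of the blank spots and bars for the mean ± SD (n = 3). Hpse stayed between 9.95 and 11.51, while M200000353 was not brighter than the blank spots on any intact array and had a mean of 13.61 in the bed at day 6.

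The bed differed from intact skin at all 3 days. Probe M200000353 was not brighter than the blank spots on any intact array. It was at least 18.8-fold higher in the bed at day 6 (limma adjusted p = 5.29e-07) and at least 9.67-fold higher at day 15 (adjusted p = 1.43e-05), and at day 2 it did not pass the threshold (adjusted p = 0.0511), although it did in 5 of 20 other settings (adjusted p from 0.0147 to 0.220 over all 20). Probe M200000214 fell. In intact skin its log2 signal was 11.91 ± 0.24 (SD, n = 3), and it was not brighter than the blank spots on any bed array of day 2 or day 6, which puts it at least 7.88-fold lower at day 2 (adjusted p = 8.73e-06) and at least 4.56-fold lower at day 6 (adjusted p = 2.63e-05). At day 15, where 1 of 3 bed arrays measured it, the log2 difference was -3.24 (SE 0.44, adjusted p = 8.02e-05), a size that rests in part on signals at the level of the blank spots. Probe M200000911 fell by 3.79 on the log2 scale at day 2 (SE 0.39, adjusted p = 2.58e-06), by 3.24 at day 6 and by 2.99 at day 15, and was measured above the blank spots on 1, 1 and 2 of the 3 bed arrays, so these sizes rest in part on signals at the level of the blank spots. For each of these calls, all 3 bed arrays lay on the same side of all 3 intact arrays. Probe M200001518, described below for the edge, was called higher in the bed at day 15 (log2 difference 2.88, SE 0.73, adjusted p = 0.0134). That call was lost with scan day as a block (2.61, adjusted p = 0.0709). In all it was lost in 5 of 20 settings, over which the adjusted p ranged from 2.5e-05 to 0.115. Its arrays overlapped, as bed replicate 1 read 8.97 and intact replicate 1 read 9.40. A bound sets the mean of the brighter group against the lowest signal that counts as above the blank spots on the dimmer group's arrays, or the probe's own signal where that is higher.

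Over all 974 tested probes, 83 were called between the bed at day 2 and intact skin (42 higher, 41 lower). At day 6 the count was 188 (91 higher, 97 lower), and at day 15 it was 117 (54 higher, 63 lower). Called probes had a median absolute log2 difference of 1.95, 1.57 and 1.64 at days 2, 6 and 15. With only the arrays of the groups compared, the counts were 115, 85 and 38, so the day with the most calls depended on this setting. At day 2 the split was 36 higher and 58 lower with the 75th percentile over the probes detected on all arrays as the scale, 54 higher and 40 lower with the 75th percentile of each array, and 55 and 39 with the deposited table. With the 75th percentile of each array, the split at day 6 was 89 higher and 55 lower, and with the median of each array it was 47 higher and 98 lower, and at day 15 it was 54 higher and 44 lower with the deposited table, so the balance of rises and falls depends on the scaling. Bed and intact arrays share only scan day 2, on which 100%, 100% and 98.3% of the called probes went the same way. These arrays took part in the calls, and in 83, 176 and 111 of the called probes the arrays of the groups did not overlap (chance gives 10% of all probes), so the direction on scan day 2 was largely set by the call. With scan day as a block 70, 77 and 49 probes were called. The median absolute log2 difference of the probes called without the block was then 2.01, 1.42 and 1.54, and the median SE over the tested probes went from 0.412 to 0.478. Without intact replicate 1 or 3, 116 or 98 were called at day 6, and without intact replicate 3 or bed day 15 replicate 3, 50 or 71 were called at day 15.

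The lists of called probes overlapped between days. Between the bed at day 2 and at day 6, 51 probes were called in the same direction and none in the opposite one, between day 2 and day 15 there were 34 and 1, and between day 6 and day 15 there were 85 and 1. Independent lists of these sizes would share 8.01, 4.98 and 11.3. In simulated data without any difference, with intact arrays that were also simulated and shared between the comparisons, at most 0.02 calls were shared. Such data give few calls at all, so this number was set in advance. It does not show how many calls shared controls add where groups differ. The covariances of the log2 differences over all tested probes were 0.589, 0.451 and 0.770, against simulated values of 0.122, 0.122 and 0.121. The correlations were 0.612, 0.527 and 0.799, against 0.510, 0.508 and 0.506. Shared controls add the same covariance with or without real effects, but not the same correlation. The 3 intact arrays could not be split into sets of at least 2 each, so part of the excess of shared calls may come from the shared controls. The covariances in excess of the simulated ones were 0.467, 0.329 and 0.649. They leave out what the shared controls add in the simulation, which gave each probe 1 spread for all groups. The simulation held no effect of scan day. The bed groups were alike in their scan days and differed in them from intact skin, so an effect of scan day would stay in the excess.

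The edge differed from intact skin at few probes. Probe M200000353 was higher in the edge too, at least 2.71-fold at day 2 (limma adjusted p = 0.0155), 7.94-fold at day 6 (adjusted p = 1.04e-05) and 2.94-fold at day 15 (adjusted p = 0.00198). Probe M200001518 had a log2 signal of 8.68 ± 0.75 in intact skin (SD, n = 3), where 1 of 3 arrays measured it above the blank spots. It was higher in the edge by 4.06 at day 2 (SE 0.73, adjusted p = 0.0155), by 3.38 at day 6 (adjusted p = 0.0169) and by 3.38 at day 15 (adjusted p = 0.0124), with all 3 edge arrays above all 3 intact arrays each time. These sizes rest in part on intact signals at the level of the blank spots. At day 2 both calls were lost when intact replicate 2 or 3 or edge replicate 1 or 2 was left out (adjusted p = 0.0988, 0.128, 0.0608 and 0.103 for M200001518, and 0.116, 0.128, 0.0608 and 0.103 for M200000353), without background correction (adjusted p = 0.0541 for both) and with the deposited table (adjusted p = 0.0740 for both). The call of M200001518 was lost at day 6 without intact replicate 2 or 3 or edge replicate 1 (adjusted p = 0.0633, 0.145 and 0.0872), and at day 15 without intact replicate 3 or edge replicate 1 or 2 (adjusted p = 0.114, 0.0518 and 0.0678). Without the 3 dimmest arrays, the calls of M200001518 at days 6 and 15 (adjusted p = 0.0965 and 0.103) and of M200000353 at days 2 and 15 (adjusted p = 0.120 and 0.0714) were lost too. Probe M200000911, which fell in the bed, was also called lower in the edge at day 15 (log2 difference -1.655, SE 0.39, adjusted p = 0.0255). With scan day as a block this call was lost (adjusted p = 0.0514).

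The edge counts were 4 probes at day 2 (3 higher, 1 lower), 14 at day 6 (11 higher, 3 lower) and 18 at day 15 (13 higher, 5 lower). At an unadjusted p below 0.05 the numbers were 94, 99 and 106 of 974 (a share of 0.05 by chance). On scan day 1 and on scan day 2 all of the called probes went the same way, which was set by the call, as the arrays of the groups did not overlap in any of them (10% of all probes by chance). With scan day as a block 3, 16 and 13 probes were called. At day 2, no probe was called without intact replicate 2 or 3 or without edge replicate 1 or 2, and 9 were called without edge replicate 3. Without intact replicate 3, 7 and 10 were called at days 6 and 15, without intact replicate 2 or edge replicate 3, 9 were called at day 6, and without edge replicate 2, 9 were called at day 15. The 75th percentile scales gave 2 higher and 0 lower at day 2, and the median scale 15 higher and 2 lower at day 15. Bed and edge shared 0 called probes at day 2, 9 at day 6 and 8 at day 15, all in the same direction. Independent lists would share 0.171, 1.33 and 1.04. The simulated data without any difference shared at most 0.06, which was set in advance, as such data give few calls. The covariances of bed and edge were 0.156, 0.314 and 0.285, against simulated values of 0.121, 0.121 and 0.122, and the correlations of 0.273, 0.460 and 0.457 lay below the simulated 0.504, 0.504 and 0.506.

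**Figure D4:**
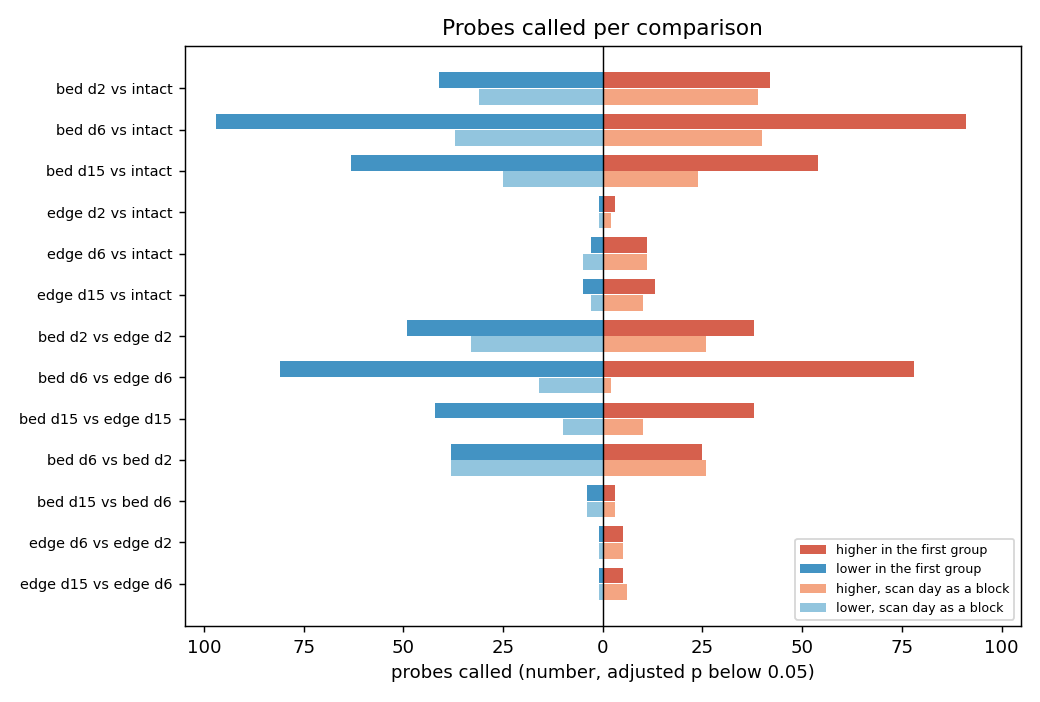
Number of probes called (adjusted p below 0.05) in each of the 13 comparisons, higher to the right and lower to the left, without (dark) and with (light) scan day as a block. The bed at day 6 had 188 calls against intact skin and 77 with the block, and 159 against the edge and 18 with the block.

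Bed and edge differed from each other at many probes. Probe M200001518 was not brighter than the blank spots on any bed array of day 2, and it was at least 14-fold lower there than in the edge (limma adjusted p = 8.67e-05), with all 3 bed arrays below all 3 edge arrays. Probe M200000214 was at least 5.48-fold lower in the bed than in the edge at day 2 (adjusted p = 6.54e-05) and at least 2.26-fold lower at day 6 (adjusted p = 0.00154). Probe M200000911 was lower in the bed by 2.64 on the log2 scale at day 2 (SE 0.39, adjusted p = 0.000155), where it was above the blank spots on 1 of 3 bed arrays, so the size rests in part on signals at the level of the blank spots. These 4 differences stayed past the threshold with scan day as a block (adjusted p = 0.00159 for each at day 2 and 0.0274 for M200000214 at day 6), as did those of M200000911 at day 6 (adjusted p = 0.00126, and 0.00978 with the block) and of M200000214 at day 15 (0.000649 and 0.0135). Other calls of these probes were lost with the block. At day 6, M200001518 had a log2 difference between bed and edge of -2.19 (SE 0.73, adjusted p = 0.0459, above the blank spots on 1 of 3 bed arrays), and with the block of -2.22 (SE 0.88, adjusted p = 0.246). At day 15, M200000911 had -1.34 (SE 0.39, adjusted p = 0.0364), and with the block -1.66 (SE 0.50, adjusted p = 0.0864), and M200000353 had 1.72 (SE 0.48, adjusted p = 0.0339), and with the block 1.53 (SE 0.62, adjusted p = 0.235).

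In number, 87 probes were called at day 2 (38 higher in the bed, 49 lower), 159 at day 6 (78 higher, 81 lower) and 80 at day 15 (38 higher, 42 lower). No bed array was scanned on scan day 1 and no edge array on scan day 3, so the comparison is free of the scan day only on scan day 2, with 1 bed and 1 edge array per day. The edge arrays of days 2 and 15 on that scan day were dim (signal 1.26 and 1.25 times the local background). Dimness and tissue are therefore not separated in them. On scan day 2, 100%, 98.7% and 100% of the called probes went the same way, with median log2 differences of 1.63, 1.21 and 1.64. These arrays took part in the calls, and in 85, 153 and 79 of the called probes the arrays of the groups did not overlap (10% by chance), so this direction too was largely set by the call. With scan day as a block 59, 18 and 20 probes were called (26 higher and 33 lower, 2 and 16, and 10 and 10). With only the arrays of the groups compared, 109, 44 and 36 were called, with 12 higher and 32 lower at day 6. At day 6 the median absolute log2 difference of the called probes went from 1.52 to 1.13 with the block, and the median SE over the tested probes from 0.412 to 0.509. The split at day 6 was 82 higher and 52 lower with the 75th percentile as the scale, 87 and 43 with the 75th percentile over the probes detected on all arrays, 43 and 74 with the deposited table, and 22 higher and 101 lower with the median. At day 2 it was 25 higher and 60 lower with the 75th percentile over the probes detected on all arrays, and at day 15 it was 23 higher and 62 lower with the median. Without edge day 2 replicate 2, 54 were called at day 2. Without bed replicate 2 or edge replicate 1, 2 or 3, 65, 76, 52 or 99 were called at day 6, and without bed replicate 3 or edge replicate 1, 2 or 3, 50, 39, 47 or 37 at day 15.

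Over time, more probes were called in the bed between day 2 and day 6 than between day 6 and day 15. Probe M200000353 rose by 3.83 on the log2 scale in the bed between these days (SE 0.48, limma adjusted p = 6.70e-05), with all 3 arrays of day 6 above all 3 of day 2. Probe M200001518 was not brighter than the blank spots on any bed array of day 2, and it was above the blank spots on 1 of 3 bed arrays at day 6 and on 3 of 3 at day 15, where its log2 signal was 11.56 ± 2.28 (SD, n = 3). Of the 3 bed arrays of day 15, replicate 1 read 8.97 and the other 2 read 12.44 and 13.27. The limit was set by each array's own blank spots. Bed day 6 replicates 2 and 3 read 9.89 and 9.00 and were below it, while the 8.97 was above it. The numbers of arrays above the blank spots therefore do not by themselves show a rise from day 6 to day 15. That change was not called (log2 difference 1.70, SE 0.73, limma adjusted p = 0.346).

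Between day 2 and day 6, 63 probes were called in the bed (25 higher at day 6, 38 lower), and between day 6 and day 15, 7 were called (3 higher, 4 lower). In the edge, 6 were called in each step (5 higher, 1 lower). At an unadjusted p below 0.05 there were 49 of 974 between day 6 and day 15 (a share of 0.05 by chance). These comparisons are balanced for scan day, and with it as a block 64, 7, 6 and 7 were called. All of the called probes went the same way on each of the scan days that hold the groups compared, but these arrays took part in the calls, and in 60, 7, 6 and 6 of the called probes the arrays of the groups did not overlap (10% by chance). The median scale gave 17 higher and 55 lower in the first step of the bed, and the 75th percentile scale 28 higher and 24 lower (29 and 20 over the probes detected on all arrays). In the second step the median scale gave 4 higher and 1 lower, the 75th percentile over the probes detected on all arrays 2 and 1, and the deposited table gave 3 and 2. In the edge the 75th percentile gave 5 higher and 2 lower in the first step (4 and 2 over the probes detected on all arrays), and in the second the median gave 5 and 0 and the deposited table gave 5 and 2. Without bed day 2 replicate 1 or 2, 34 or 38 were called in that step, and without bed day 6 replicate 1, 2 or 3, 31, 33 or 99. In the second step 12 were called without bed day 6 replicate 3 and 26 without bed day 15 replicate 1. In the edge, 10 were called between day 2 and day 6 without edge day 2 replicate 3, and 2 or 3 between day 6 and day 15 without any 1 of the 6 arrays. Whether the difference between bed and edge changed with the day was tested with an F-test of limma, which called 13 of the 974 probes (14 with scan day as a block), among them M200001518 (adjusted p = 0.0441), whose call was lost in 20 of 32 other settings (adjusted p up to 0.169). The F-test called 4 with same-numbered bed and edge arrays of a day treated as pairs, and 4 with only the arrays of bed and edge. Leaving out 1 of the 18 bed and edge arrays moved the count by over 1.5 times in 12 fits, to 54 without bed day 15 replicate 1 and to between 4 and 8 in the other 11.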

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

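The tests of scan day, of labels and of similar arrays in this part were chosen after the results, or closely related ones, had been seen, and the counts of other splits of the samples before.

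The first results were singled out because the difference between bed and edge itself differed between days. The F-test called 13 of 974 probes. Among 100 random relabellings of bed and edge within each day, the real one included, 6 called as many, and the highest other count was 90. Such relabelling mixes bed and edge arrays differently on each day, so the difference between the tissues itself enters the test, and the relabelled sets do not decide whether chance gave the 13. Since that difference alone can raise the count, the 90 points to no further structure of the samples. Probe M200001518 had an adjusted p of 0.0441 in that test. It was not brighter than the blank spots on any bed array of day 2, where it was at least 14-fold lower than in the edge, so the test rests in part on signals at the level of the blank spots. The log2 difference between bed and edge was -2.19 at day 6, with 1 of 3 bed arrays above the blank spots, and -0.49 at day 15. The call was lost in 20 of 32 other settings, over which the adjusted p ranged from 9.00e-05 to 0.169, and it was lowest without bed day 15 replicate 1.

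For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real split called 83, 188 and 117 probes for the bed against intact skin at days 2, 6 and 15, and the highest other split 0, 0 and 1. For the edge it called 4, 14 and 18 against 0 in any other split, and for bed against edge 87, 159 and 80 against 0. Over time it called 63 in the bed from day 2 to day 6 (highest other 1), and 6 and 6 in the edge (highest other 0). In each of these 12 comparisons 1 of the 10 splits, the real one, reached the real count. For the bed from day 6 to day 15, 4 of the 10 splits called at least the 7 of the real split, and the highest called 70. That split set bed day 6 replicates 1 and 3 and bed day 15 replicate 2 against the others, which follows neither day nor scan day and points to a structure of these 6 samples other than the day.

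Bed and edge differed at fewer probes once scan day was a block, 18 in place of 159 at day 6. An effect of scan day as the whole cause is argued against by an independent set of arrays. Of the probes called from scan days 1 and 3 alone, 92.4% of 79, 86.8% of 114 and 92.3% of 26 went the same way on scan day 2 at days 2, 6 and 15, with median differences in the called direction of 1.45, 0.98 and 1.65 on the log2 scale (lower quartiles 0.78, 0.39 and 0.93), where the scan day alone would give about an even split. Part of the difference may still come from the scan day, since at day 6 the median fell from 1.92 to 0.98, although probes picked for a large difference also fall back by chance. The loss of calls may also come from the larger error of the blocked difference, and this cannot be told apart from a smaller difference, because 69 of the 159 probes passed with the blocked difference and the unblocked error, and 82 with the unblocked difference and the blocked error. A difference between the tissues stays open as the biological explanation.

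Bed day 15 replicate 1 resembled the bed at day 2. Its scan day does not account for this, since its mean r with the bed day 2 arrays of scan day 3 was 0.882, above the highest r with the other bed day 15 arrays (0.846), which were also scanned on day 3. A swap of labels between the 2 groups is argued against too, because every bed day 2 array correlated better with its own group than with bed day 15 replicates 2 and 3, by at least 0.174. A single wrong label, or a wound that healed more slowly, may each give this pattern, in which r with bed day 2 exceeded that with the own group by 0.0906, and they cannot be told apart here because no second sample of the same animal is identified. Other arrays also correlated better with another group than with their own, though by less. Bed day 15 replicate 2 did so with edge day 15 (mean r 0.863 against 0.837), and bed day 6 replicate 3 with bed day 2 (0.851 against 0.838). Bed day 15 replicates 2 and 3 had an r of 0.827 with each other, below the 0.846 above. The pattern by itself therefore does not mark a wrong label.

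Edge replicates 1 and 2 of day 2 and of day 15 resembled each other across days (r 0.961 to 0.965). All 4 were scanned on day 1. Edge day 6 replicates 1 and 2, scanned on the same day, reached at most 0.936 with these 4. But these 2 correlated with each other at only 0.920, although they share both group and scan day. Their lower r with the 4 therefore cannot decide whether scan day is the whole cause, and whether it has a part stays open. Edge replicates 3 of day 2 and day 15, scanned on day 2, correlated with the 4 at 0.850 to 0.937, those of their own day included, but these 2 arrays were also dim (signal 1.26 and 1.25 times the local background, against 1.61 to 1.82 for the 4), and the effects of scan day and of dimness cannot be told apart in them. No biological explanation was tested, and 4 probes were called between the edge at day 15 and at day 2.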

How the results depend on the processing

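The settings without background correction, with the median over spots, with flag 1 spots kept and without the 3 dimmest arrays were chosen after the data had been seen. Comparisons are named in the order bed against intact skin, edge against intact skin, bed against edge (each at days 2, 6 and 15), bed from day 2 to 6 and 6 to 15, edge from day 2 to 6 and 6 to 15, and the test for a change of the bed and edge difference with the day. The counts of these were 83, 188, 117, 4, 14, 18, 87, 159, 80, 63, 7, 6, 6 and 13. The cause of a change was not tested unless stated. Signal over background limits what can be seen, since 323 of 1687 probes were detected on all 21 arrays.

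Restricted to those 323 probes, the counts were 15, 47, 33, 0, 3, 0, 9, 43, 7, 18, 1, 0, 1 and 0. Fewer probes were tested, but the share called was lower too, as with 9 of 323 against 87 of 974 for bed against edge at day 2. This setting leaves out every probe that was at the level of the blank spots on any array, and many calls were of such probes. At an adjusted p below 0.01, a stricter threshold, they were 47, 74, 41, 0, 8, 10, 52, 26, 33, 19, 2 (bed from day 6 to 15), 2 (edge from day 6 to 15) and 4 (change with the day). With only the arrays of the groups compared, 115, 85 and 38 were called for the bed against intact skin at days 2, 6 and 15. For bed against edge the counts were 109, 44 and 36. The edge at day 15 against intact skin had 40, the bed over time 14 and 1, and the change with the day 4. In both comparisons of the bed, the counts of day 2 rose and those of days 6 and 15 fell. The day with the most calls was then day 2 in place of day 6. With scan day as a block, 77 and 49 were called for the bed against intact skin at days 6 and 15, and 18 and 20 for bed against edge at days 6 and 15, of which 71, 46, 17 and 19 were also called without the block.

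For the edge at day 2 against intact skin, 2 were called with the 75th percentile, 2 with the 75th percentile over probes detected on all arrays, 0 with the deposited table, 0 without background correction and 7 without the 3 dimmest arrays, which also gave 11 for the edge from day 2 to 6. The 75th percentile over probes detected on all arrays gave 125 for the bed at day 6 against intact skin and 3 for the bed from day 6 to 15. Median scaling moved the median log2 difference of all tested probes by over 0.1, to -0.29 for the bed at day 6 against intact skin, to 0.10 for the edge at day 15 against intact skin, to -0.37 and -0.20 for bed against edge at days 6 and 15, and to -0.21 and 0.20 for the bed from day 2 to 6 and 6 to 15, against -0.02, -0.02, -0.04, -0.01, -0.05 and 0.05 with quantiles, relative to which changes are reported. Over all 13 comparisons it lay between -0.05 and 0.06 with quantiles, between -0.37 and 0.20 with median scaling, between -0.09 and 0.10 with the 75th percentile and between -0.22 and 0.26 with the 75th percentile over probes detected on all arrays.

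The arrays showed no sign that the replicate numbers pair bed and edge, but a pairing by animal is not excluded. Same-numbered bed and edge arrays were never scanned on the same day, and the labels do not say whether they share an animal. The deviations of same-numbered arrays from their group means correlated between -0.244 and 0.0786 over 9 pairs, of which 0 were above 0.1. For the edge at day 2 against intact skin, the block by replicate number called 2. For the bed from day 6 to 15 it called 3. With same-numbered bed and edge arrays of a day treated as pairs, 97 were called for bed against edge at day 6. The change with the day then had 4. No other count moved by over 1.5 times with these blocks.

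Leaving out each array in turn gave ranges of 59 to 76, 98 to 211 and 50 to 134 for the bed against intact skin, 0 to 9, 7 to 14 and 9 to 19 for the edge, 54 to 97, 52 to 163 and 37 to 103 for bed against edge, 31 to 99 and 5 to 26 for the bed over time, and 4 to 10 and 2 to 3 for the edge over time. For the change with the day the range was 4 to 54. It was 8, 5 or 6 without bed day 2 replicate 1, 2 or 3, 7 or 4 without bed day 6 replicate 1 or 2, 54 or 8 without bed day 15 replicate 1 or 2, 8 without edge day 2 replicate 2, 4, 4 or 5 without edge day 6 replicate 1, 2 or 3, and 4 without edge day 15 replicate 2. Where 2 arrays of a group were left, the spread was pooled over the groups.

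Of 28 differences of single probes, 18 kept their side of the threshold in every setting in which they were tested, and 10 did not. Over 578 settings of these, 61 lost a call, 7 gained one and 0 changed sign. The falls of M200000214 and M200000911 in the bed kept their calls throughout, with adjusted p of at most 0.0119. Not run were the slide as a block (21 slides of 1 array), centring on reference genes, the mean over probes of a gene, and the tests of gene lists with their alternatives. All but the first of these need gene symbols, and 3 of the 1687 probes were matched to one.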

Other observations

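The test in this part was chosen after its result had been seen.

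Between the bed at day 15 and the bed at day 2, 65 probes were called by limma (31 higher at day 15, 34 lower), against 7 between day 15 and day 6. In the edge 4 probes were called between day 15 and day 2, and 36 of 974 had an unadjusted p below 0.05 (a share of 0.05 by chance).

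Taken over the 3 days together, 292 probes were called between the 9 bed and the 9 edge arrays (143 higher in the bed, 149 lower). With scan day as a block 31 were called, and with the 6 arrays of scan day 2 alone 5. The median log2 difference of the 292 in the called direction was 0.80 in each of these fits, against 1.01 over all arrays. Bed and edge share only scan day 2, so both fits take the difference between the tissues from the same 6 arrays. Their equal values were set by the design and are not separate evidence. The arrays of scan day 2 took part in the 292 calls, so the direction in these fits was largely set by the call.

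A hypothesis was that the probes with public identifiers had been chosen for the study and changed more often. Of the 43 such probes tested, 9 were called in the bed at day 6 against intact skin, against 179 of the other probes. The odds ratio was 1.11 (95% interval 0.461 to 2.42), and Fisher's exact test, two-sided, gave p = 0.843 (Benjamini-Hochberg adjusted p = 1 over 9 comparisons). The interval leaves both a lower and a higher share open.

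None of the 328 blank or empty positions was brighter than the median probe on over 50% of the arrays.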
